A study of Sus scrofa with 24 samples.

How the data were processed

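Total RNA from longissimus dorsi muscle of 24 crossbred pigs was measured with a 1-colour Affymetrix oligonucleotide array that carries porcine probe sets, 1 array per pig. The labels give the dietary fat (beef tallow, coconut oil, olive oil or soybean oil, added at 3.0% of the feed) and the sex (gilt, a young female, or barrow, a castrated male). Each combination of fat and sex held 3 pigs, so each fat had 6 pigs and each sex 12. The labels describe 24 pens, 6 per fat with 3 pigs each. The pen of each sampled pig is not given in the sources used here, so pigs were treated as independent and no SE or p allows for pens. Pigs are called by the running number of their sample title; gilts carry numbers 1 to 12 and barrows 13 to 24. All 24 arrays were used and none was left out.

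The deposited values are probe set signals in linear intensity units. The authors' labels name no summarisation algorithm and no scaling. On the values themselves, the mean after trimming 2% of the probe sets at each end lay between 500.1 and 500.2 on every array, while array medians lay between 139 and 174. The arrays were thus scaled to a common trimmed mean and were not quantile normalized. The table held 24123 probe sets, of which 124 were controls. Signals were turned into log2(signal + 1), and 14399 of the 23999 other probe sets were tested, those with a mean over all arrays at or above the 40th percentile (a signal of 86.3). Arrays give no counts, so the number of pigs limits the precision.

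Gene symbols came from the probe set annotation supplied for the array; 9989 of the 10099 probe sets with 1 symbol had a gene identifier in the RefSeq annotation of assembly Sscrofa11.1, which was used for current names and synonyms alone. Of the probe sets other than controls, 10069 had 1 symbol, 198 had several and 13732 had none. The tested probe sets with 1 symbol stood for 5345 genes.

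Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on 8 group means, 1 per combination of fat and sex). The tests were the 6 pairs of fats averaged over the sexes, the mean of olive and soybean oil minus the mean of beef tallow and coconut oil, barrow minus gilt averaged over the fats, a moderated F test over the 4 fats, and a moderated F test of the interaction of fat and sex. All tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold within each test. At an unadjusted p under 0.05, chance gives about 720 of the probe sets.

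There were 24 gene lists: lipogenesis and triglyceride synthesis, adipocyte markers, fatty acid oxidation, targets of the nuclear receptor family PPAR, oxidative phosphorylation, the tricarboxylic acid cycle, glycolysis and glycogen, cholesterol synthesis, slow fibre genes, fast fibre genes, fibroblast and extracellular matrix, leukocyte markers, interferon response, erythrocyte markers, endothelial markers, satellite cells and regeneration, atrophy and FOXO targets, heat shock and chaperones, immediate early genes, the circadian clock, the growth axis, Y-linked genes, X-linked genes with a Y partner, and ribosomal proteins. The 22 lists with at least 5 tested genes were tested with camera of limma, with the highest-mean probe set of each gene and a preset correlation of 0.01, and again with a correlation estimated from the data. Camera compares a list with the other genes. Each list was also scored per pig as the mean log2 value of its tested genes, centred over the 24 pigs. Scores were compared by exact permutation of the fats within each sex (400 relabelings for a pair, smallest p 0.005) or of the sexes within each fat (160000 relabelings, smallest p 1.25e-05). These p were adjusted over the 132 tests of the fat pairs, or over the 22 tests of a single contrast. Where members of a list were adjusted over that list alone, the other lists and probe sets were not allowed for. Members of a list can change together, so such counts are not separate findings.

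The tests, the lists, the alternatives and the rule for the genes to be named were set before the data were examined, apart from the alternatives said below to be added later and the per-pig score tests. The rule took, among probe sets with 1 symbol past the threshold, the 5 largest positive and 5 largest negative differences of each pair of fats and the 12 largest in each direction between the sexes. Where fewer than 8 passed, the 8 smallest p are given as values that did not pass. It always took SCD, FASN, PPARG, PPARGC1A, CPT1B, PDK4, UCP3, LPL, FABP4, ADIPOQ, LEP, MYH7 and IGF1, and the 4 members with the smallest p of each list past the threshold. ACACA, FADS2, SREBF1 and PPARA, also in the rule, lay below the signal filter, and no probe set was named DDX3Y or XIST.

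The alternatives were no signal filter, a filter at the 60th percentile, quantile normalization, centring of each array on its median, a pseudocount of 16, an additive model of fat plus sex, trended and robust spread, array weights, 1 probe set per gene, the 12 arrays of a pair alone, the estimated list correlation, and leaving out each pig in turn. For the gene lists, median centring and the pseudocount were added after the data were seen, as was leaving out the 3 arrays with the lowest mean correlation with the others (pigs 11, 12 and 16). The slow fibre score without each of its genes in turn, the setting of pigs below the signal filter to its level and the comparison of interferon and endothelial scores were also added later. The filter is a percentile and no measure of background. Counts were also compared with those from 99 random regroupings of the same pigs. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables, permutations and plots.

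The model was tested on simulated data with the same 14399 probe sets and groups. For coconut oil minus beef tallow, 97 of 100 changes of 2 on the log2 scale and 75 of 100 changes of 1 were called, with 6 false calls. For barrow minus gilt, 91 of 100 changes of 1 and 37 of 100 changes of 0.5 were called, with 7 false calls. Without simulated changes there were 0 calls in either comparison. The simulated noise was drawn independently for each probe set, so correlation between genes was left out. Random regroupings of the real pigs called up to 1 probe set for coconut oil minus beef tallow and up to 74 for barrow minus gilt. The highest count for a pair of fats was 708, for olive oil minus beef tallow. The simulation therefore does not give the false calls to be awaited on the real arrays.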

Results

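Gene expression was measured in longissimus dorsi, the main muscle of the loin, of 24 pigs fed 1 of 4 dietary fats (6 pigs per fat, 3 gilts and 3 barrows each). The pigs weighed about 71 kg at an age of about 130 days when they were allotted to the diets. Pearson correlations of log2 signals between pairs of arrays lay between 0.863 and 0.967, and pigs 12, 11 and 16 had the lowest mean correlations with the other arrays (0.907, 0.925 and 0.927). The median signal of an array was 162 ± 7.27 with beef tallow, 148 ± 6.69 with coconut oil, 152 ± 9.85 with olive oil and 158 ± 7.51 with soybean oil (SD, n = 6). The log2 median was lower with coconut oil than with beef tallow by a difference of -0.13 (exact permutation p = 0.015), and the barrow minus gilt difference was -0.05 (exact permutation p = 0.132). The ratio of the 3' to the 5' probe sets of GAPDH, a measure of RNA integrity, lay between 1.02 and 1.25, with exact permutation p of 0.48 for coconut oil minus beef tallow and 0.599 for barrow minus gilt. That of actin was higher, from 0.88 to 1.84 on the log2 scale with pig 16 highest (exact permutation p = 0.55 and 0.68 for these differences).

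The series asks how types of dietary fat affect gene expression in pork. In muscle of pigs fed coconut oil, 7 of 22 fibroblast and extracellular matrix genes fell against beef tallow. POSTN, which encodes the matrix protein periostin, fell by 1.60 ± 0.37 on the log2 scale (SE, 6 pigs per fat), a 3.02-fold difference. THY1, a surface protein of fibroblasts, fell by 0.95 ± 0.17. FBN1, the microfibril protein fibrillin 1, and DCN, the collagen-binding proteoglycan decorin, differed by -0.69 ± 0.15 and -0.71 ± 0.17 and also passed (adjusted p of the 4 genes from 0.0303 to 0.0477). For each of these 4 genes, 6 of 6 pigs fed coconut oil lay below the mean of the pigs fed beef tallow. The genes were chosen on this comparison, and the groups overlapped for DCN. Of the 22 members of the list, 15 did not pass; 20 fell when adjusted over the list alone, and 21 of 22 differences were negative. The list median was -0.69 (camera adjusted p = 7.61e-11; adjusted p = 0.876 with an estimated correlation). The list score per pig was 0.32 ± 0.36 with beef tallow and -0.41 ± 0.16 with coconut oil (SD, n = 6; exact permutation p = 0.005, the smallest that the relabelings can give; adjusted p = 0.165), and all 6 pigs fed coconut oil scored below all 6 fed beef tallow. Scores of 2 other non-muscle cell types also had negative differences: the leukocyte score differed by -0.32 (exact permutation p = 0.2) and the endothelial score by -0.21 (exact permutation p = 0.105).

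Lists of fat cells and fat synthesis had negative medians with coconut oil as well. FABP4, the fatty acid carrier of adipocytes, fell by 1.09 ± 0.27 on the log2 scale (limma adjusted p = 0.0483). It was lower in 6 of 6 pigs than the beef tallow mean, but the groups overlapped. ADIPOQ, which encodes the adipocyte hormone adiponectin, differed by -1.91 ± 0.58, PPARG, the main regulator of adipocyte formation, by -1.40 ± 0.40, and CIDEA, a lipid droplet protein, by -1.15 ± 0.35; these did not pass (adjusted p = 0.081, 0.0708 and 0.086). Of 12 adipocyte markers, 1 fell and 11 did not pass; adjusted over the list alone, 5 fell and 1 rose. The list median was -1.08 (camera adjusted p = 0.0106; adjusted p = 0.876 with an estimated correlation) and the score differed by -0.90 (exact permutation p = 0.02; adjusted p = 0.264). In the list of lipogenesis and triglyceride synthesis, 0 of 12 genes passed over all probe sets and 6 fell when adjusted over the list alone. Its median was -0.48 (camera adjusted p = 0.029; adjusted p = 0.876 with an estimated correlation). The score of that list differed by -0.80 (exact permutation p = 0.02; adjusted p = 0.264). Its members FASN, the fatty acid synthase, DGAT2, which completes triglycerides, and ELOVL6, a fatty acid elongase, differed by -2.02 ± 0.58, -2.07 ± 0.58 and -1.86 ± 0.54, and SCD, which desaturates fatty acids, by -2.16 ± 0.80 (adjusted p = 0.14). The lipogenesis list no longer passed without pig 8, 21 or 24. Its median lay between -0.61 and -0.37 over the 24 runs that left out a pig. Only runs without a pig fed coconut oil or beef tallow could move this median.

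**Figure D1:**
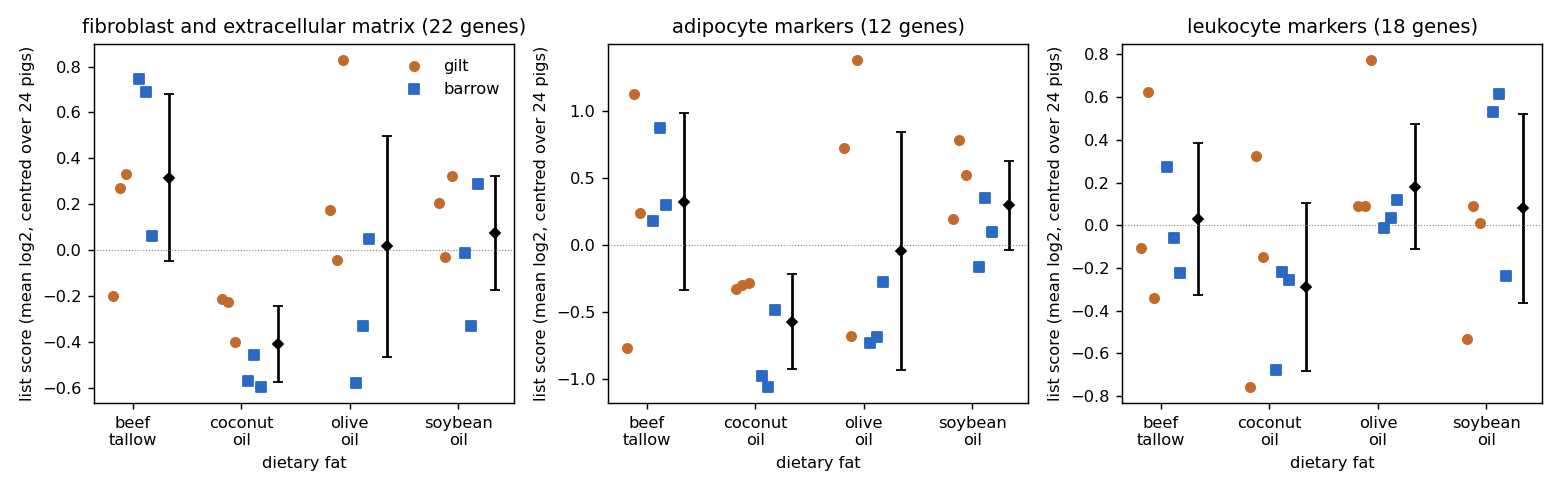
List scores per pig (mean log2 value of the list's genes, centred over the 24 pigs) for fibroblast and extracellular matrix genes, adipocyte markers and leukocyte markers by dietary fat; circles are gilts, squares are barrows, and diamonds with bars are the mean ± SD of 6 pigs. Mean matrix scores were 0.32 with beef tallow, -0.41 with coconut oil, 0.02 with olive oil and 0.07 with soybean oil.

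Other genes changed in both directions with coconut oil against beef tallow. NR4A3, a nuclear receptor and immediate early gene, rose by 2.12 ± 0.44 on the log2 scale, and GLUL, the glutamine synthetase, rose by 1.31 ± 0.29. SAMD4A, an RNA-binding repressor of translation, CUL4A, a scaffold of ubiquitin ligases, and CBARP, a regulator of calcium channels, rose by 0.84, 0.82 and 0.79; the other probe set of CBARP had the opposite sign. SFRP1, a secreted inhibitor of Wnt signals, fell by 1.90 ± 0.41, and PSAT1, an enzyme of serine synthesis, fell by 1.49 ± 0.33. C3H2orf40 and DSE, which makes dermatan sulfate, differed by -2.71 ± 0.62 and -1.84 ± 0.44, but 3 and 4 of the 6 pigs fed coconut oil lay below the signal filter for them. With these pigs set to the filter level, C3H2orf40 and DSE fell by at least 2.29 and 0.72. Adjusted p of these 9 genes lay between 0.0378 and 0.0479, and for each of them 6 of 6 pigs fed coconut oil lay beyond the beef tallow mean. The genes were chosen on this difference, and the groups overlapped for GLUL, CUL4A, DSE and PSAT1. Lists of energy metabolism had small positive medians: 0.20 for the tricarboxylic acid cycle, 0.19 for fatty acid oxidation, 0.12 for glycolysis and 0.11 for oxidative phosphorylation (camera adjusted p = 0.00116, 0.0299, 0.0422 and 0.0219; adjusted p = 0.876 for the first and 0.902 for the others with an estimated correlation). The scores of these lists had exact permutation p of 0.075, 0.455, 0.3 and 0.39 in this order. None of their members rose, and HK1, a hexokinase of many tissues that opens glycolysis, fell by 0.96 ± 0.21 (limma adjusted p = 0.0413). In the tricarboxylic acid cycle list the smallest p was that of PC, pyruvate carboxylase, with a difference of -1.11 that did not pass. The list of atrophy and FOXO targets had a median of 0.22 (camera adjusted p = 0.0106; adjusted p = 0.876 with an estimated correlation), and its members FBXO32, a ubiquitin ligase of muscle wasting, KLF15 and FOXO1 differed by 1.20, 0.75 and 0.75 without passing. The score of the atrophy list had an exact permutation p of 0.08. The lists of fatty acid oxidation and oxidative phosphorylation no longer passed without pig 1, 2, 20 or 21, with medians of 0.09 and 0.05 without pig 21. The glycolysis list no longer passed without pig 1, 8, 15, 21 or 24 (median 0.07 without pig 15), and the atrophy list without pig 24. Quantile normalization ended the calls of the fatty acid oxidation, glycolysis and oxidative phosphorylation lists, and median centring those of the first 2.

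PPARGC1A, a coactivator of mitochondrial genes, differed by 1.55 ± 0.44 (adjusted p = 0.0708). CPT1B, PDK4 and UCP3, which serve fatty acid use in muscle, differed by 0.26, 0.13 and -0.05, and LPL, LEP, MYH7 and IGF1 by -0.35, -0.13, 0.09 and -0.38; none of these passed. Medians of the lists that did not pass in this comparison were -0.52 for interferon response, -0.37 for leukocyte markers, -0.33 for the growth axis, -0.31 for satellite cells and regeneration, -0.23 for endothelial markers, -0.11 for ribosomal proteins, -0.09 for cholesterol synthesis, 0.14 for immediate early genes, 0.10 for the circadian clock, 0.09 for heat shock and chaperones, 0.07 for slow fibre genes, 0.02 for fast fibre genes and 0.03 for X-linked genes with a Y partner. PPAR targets had a median of -0.05 and a mean of -0.07, while camera placed the list on the positive side (adjusted p = 0.984). Erythrocyte markers (4 tested genes) and Y-linked genes (1 tested gene) were too few to test.

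With limma, 161 of 14399 probe sets passed for coconut oil minus beef tallow, 37 higher and 124 lower with coconut oil, which stand for 69 named genes. In all, 2857 had an unadjusted p under 0.05. The count depended on which pigs were kept. It was 0 without pig 6, 8, 16 or 21, 1 without pig 15, 2 without pig 10 and 14 without pig 1. It was 22 without pig 23, 24 without pig 20, 39 without pig 18 and 57 without pig 13. It was 93 without pig 22, 100 without pig 3 and 107 without pig 14. It was 401 without pig 24, 404 without pig 7, 407 without pig 2 and 664 without pig 12. Of these, pigs 3, 7, 12, 13, 14, 18 and 22 were fed olive or soybean oil. The log2 difference between coconut oil and beef tallow does not depend on them, but the spread estimated from all arrays does. Without the 3 least correlated arrays 260 passed, 118 of them among the 161. The call of each gene named above as changed was lost in 8 (THY1) to 20 (FABP4) of the 24 runs that left out a pig, each time without pig 1, 6, 8, 10, 15, 16 or 21. The log2 difference of NR4A3 was between 1.78 and 2.39 in these runs and that of POSTN between -1.77 and -1.45. No filter left 6 calls, quantile normalization 51 and the additive model 0. The share of calls that were lower was 77% as deposited and 70.6% after quantile normalization, but 38.4% (63 of 164) when each array was centred on its median, which moved the median difference of all probe sets by 0.126.

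The median absolute log2 difference of these 161 probe sets, which were chosen on the mean of both sexes, was 0.62 in gilts, where 0 passed (677 at an unadjusted p under 0.05, limma), and 1.26 in barrows, where 298 passed. The barrow minus gilt difference had the sign of the call in 150 of 161 and passed for 0 probe sets (796 at an unadjusted p under 0.05).

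**Figure D2:**
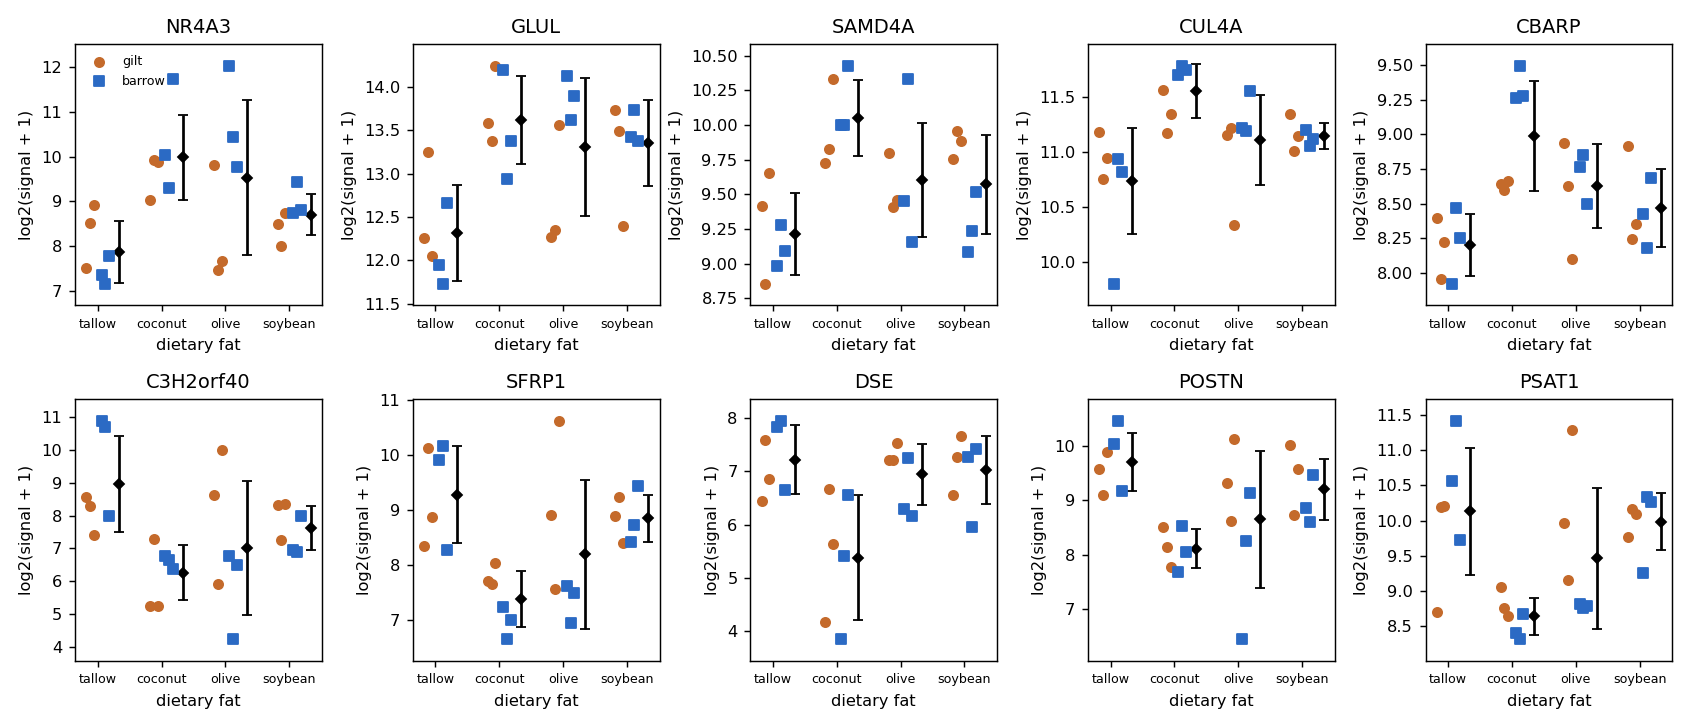
Signals per pig, as log2(signal + 1), by dietary fat for the 5 named genes with the largest positive and the 5 with the largest negative difference between coconut oil and beef tallow; circles are gilts, squares are barrows, and diamonds with bars are the mean ± SD of 6 pigs. Mean NR4A3 was 7.87 with beef tallow and 9.99 with coconut oil, and mean POSTN 9.70 and 8.11.

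The matrix and adipocyte lists had positive medians for soybean oil minus coconut oil, and no gene passed. The same 6 pigs fed coconut oil enter this comparison. Among matrix genes, THY1 differed by 0.67 ± 0.17 and POSTN by 1.10 ± 0.37. Of that list 22 of 22 members were positive (median 0.43, camera adjusted p = 1.06e-07; adjusted p = 0.876 with an estimated correlation), and 1 rose when adjusted over the list alone. Among 12 adipocyte markers, PPARG differed by 1.34 ± 0.40, FABP4 by 0.96 ± 0.27 and ADIPOQ by 1.76 ± 0.58 (median 0.99, camera adjusted p = 0.000527; adjusted p = 0.876 with an estimated correlation), and 6 rose when adjusted over the list alone. Both list scores, and that of the growth axis (0.21), which camera did not call, had an exact permutation p of 0.005, the smallest possible here (adjusted p = 0.165). Medians were 0.35 for leukocyte markers and 0.24 for endothelial markers, and -0.31 for atrophy and FOXO targets, -0.20 for the tricarboxylic acid cycle and -0.12 for oxidative phosphorylation; all 5 passed camera, with adjusted p from 0.876 to 0.902 with an estimated correlation. Their scores had exact permutation p of 0.18, 0.015, 0.02, 0.015 and 0.085 in this order, and none passed after adjustment. The leukocyte list no longer passed without pig 1, and the endothelial list without pig 6, 9, 11, 15, 19 or 20. TES, an actin-associated protein, FKBP14, a chaperone of collagen folding, CALML4, NID2, a basement membrane protein, and PSAT1 differed by 1.11, 1.01, 1.14, 0.82 and 1.34 (adjusted p from 0.18 to 0.252). No probe set passed in limma and 1875 had an unadjusted p under 0.05; 33 passed when the arrays of these fats were fitted alone, 5 with array weights, 3 without the filter, 4 without pig 12 and 1 without pig 14. Of the 13 genes named in every comparison, ADIPOQ had the highest difference and PPARGC1A the lowest (-0.63).

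Matrix and leukocyte lists had positive medians for olive oil minus coconut oil, again with no gene past the threshold. THY1 and FBN1 differed by 0.56 ± 0.17 and 0.49 ± 0.15. In all, 22 of 22 matrix genes were positive (median 0.48, camera adjusted p = 2.93e-08; adjusted p = 0.876 with an estimated correlation; score exact permutation p = 0.015, adjusted p = 0.264). CD163, a macrophage receptor, and C1QC, a complement protein made by macrophages, differed by 0.76 ± 0.27 and 0.86 ± 0.34. All 18 leukocyte markers were positive (median 0.47, camera adjusted p = 4.67e-06; adjusted p = 0.876 with an estimated correlation; score exact permutation p = 0.03, adjusted p = 0.33). Medians of the other called lists were 0.49 for adipocyte markers (score exact permutation p = 0.16, adjusted p = 0.782), 0.28 for the growth axis (score exact permutation p = 0.025, adjusted p = 0.3), 0.27 for endothelial markers (0.045, adjusted p = 0.457), -0.16 for oxidative phosphorylation, -0.17 for the tricarboxylic acid cycle and -0.19 for fatty acid oxidation; adjusted p of the 8 lists with an estimated correlation lay between 0.876 and 0.902. Scores of oxidative phosphorylation, the tricarboxylic acid cycle and fatty acid oxidation had exact permutation p of 0.305, 0.37 and 0.215. Without pig 12 the adipocyte, growth axis, oxidative phosphorylation and tricarboxylic acid cycle lists no longer passed. The adipocyte list also ended without pig 4 or 20, the growth axis without pig 5, 17, 20 or 23 and the tricarboxylic acid cycle without pig 22. FKBP14, RTN3 and SCD5, a second fatty acid desaturase, differed by 0.92, 0.63 and 1.21 (adjusted p = 0.554). With limma 0 probe sets passed and 1275 had an unadjusted p under 0.05; 2 passed without the filter and 1 without pig 1 or pig 4. The 13 genes named in every comparison ranged from -0.89 (PPARGC1A) to 1.28 (ADIPOQ).

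Between olive oil and beef tallow, no gene passed. Among immediate early genes, which cells induce first after a stimulus, NR4A3 differed by 1.51 ± 0.42 and ATF3, a stress-induced factor, by 0.94 ± 0.34. In that list 14 of 15 members were positive and 1 rose when adjusted over the list alone (median 0.54, camera adjusted p = 4.55e-08; adjusted p = 0.876 with an estimated correlation; score exact permutation p = 0.13, adjusted p = 0.746). The matrix list had a median of -0.28 (camera adjusted p = 0.000419; adjusted p = 0.876 with an estimated correlation; score exact permutation p = 0.255), with COL1A2, a chain of type I collagen, at -0.92 ± 0.35. Medians of the other called lists were 0.28 for atrophy and FOXO targets, 0.14 for leukocyte markers, 0.12 for heat shock and chaperones and -0.41 for lipogenesis. Their scores had exact permutation p of 0.145, 0.435, 0.12 and 0.155 in this order. Adjusted p of these 6 lists with an estimated correlation lay between 0.876 and 0.902. The leukocyte list no longer passed without pig 2, 10, 12 or 24, the lipogenesis list without pig 7 or 21, the heat shock list without pig 7 and the atrophy list without pig 24. C1QTNF3, a secreted relative of adiponectin, FKBP10, a collagen chaperone, SPP1, the matrix protein osteopontin, and CHRNA1, a subunit of the acetylcholine receptor, differed by -1.31, -1.05, -2.20 and -1.53 (adjusted p from 0.269 to 0.462). With limma 0 probe sets passed and 928 had an unadjusted p under 0.05; 7 passed without pig 24 and 1 without pig 8 or pig 12. The 13 genes named in every comparison ranged from -0.91 (FASN) to 0.66 (PPARGC1A).

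Between soybean oil and beef tallow, no gene passed. The immediate early list had a median of 0.28 and the matrix list one of -0.20, with ATF3 at 0.86 ± 0.34 and COL1A2 at -0.85 ± 0.35 (camera adjusted p = 0.000502 and 0.000242; adjusted p = 0.876 each with an estimated correlation). Neither list score passed (exact permutation p = 0.185 and 0.235; adjusted p = 0.803 and 0.816). The lipogenesis and ribosomal protein lists had medians of -0.31 and -0.09; all 4 had adjusted p from 0.876 to 0.902 with an estimated correlation. Lipogenesis and ribosomal protein scores had exact permutation p of 0.285 and 0.32. The immediate early list no longer passed without pig 2, the ribosomal list without pig 8 or 16, and the lipogenesis list without pig 3, 8, 9, 10, 13, 21 or 24. GLUL and PRKCA, a protein kinase C, differed by 1.04 ± 0.29 and 0.81 ± 0.21, and ABCC6, a transporter, by 0.66 ± 0.15 (adjusted p = 1 each). With limma 0 probe sets passed and 498 had an unadjusted p under 0.05; 1 passed without pig 14. The 13 genes named in every comparison ranged from -1.10 (SCD) to 0.92 (PPARGC1A).

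Between soybean oil and olive oil, the 13 genes named in every comparison ranged from -0.20 (SCD) to 0.50 (PPARG), and no gene passed. Medians of the 3 called lists were -0.25 for atrophy and FOXO targets, -0.20 for immediate early genes and -0.11 for heat shock and chaperones (camera adjusted p = 0.000419, 0.00874 and 0.0026; adjusted p = 0.876 each with an estimated correlation), with CEBPD, a transcription factor, at -0.78 ± 0.29. Atrophy, immediate early and heat shock scores had exact permutation p of 0.16, 0.36 and 0.225. The heat shock list no longer passed without pig 7 and the immediate early list without pig 17 or 18. The smallest p of a named gene was that of SMG9, a factor of RNA decay (0.54 ± 0.13, adjusted p = 1). No probe set passed in limma and 458 had an unadjusted p under 0.05; 1 passed without pig 14.

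Across all 4 fats, no gene passed the F test. FKBP14 and FKBP10, chaperones of collagen folding, THY1 of fibroblasts and NID2 of the basement membrane were among the genes with the smallest p. The 8 named genes with the smallest p were FKBP14, THY1, FKBP10, C1QTNF3, TES, FGD4, ABCC6 and NID2 (adjusted p from 0.156 to 0.202), and those of the 13 genes named in every comparison were 0.222 (FABP4) and above. With limma 0 probe sets passed and 1676 had an unadjusted p under 0.05; 4 passed without the filter, 68 with array weights, 11 without pig 12, 25 without pig 24 and 1 without pig 14.

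The oils rich in unsaturated fatty acids (olive, soybean) were set against the fats rich in saturated ones (beef tallow, coconut oil). No list score passed. SLA-DQA1, which presents antigen, and C1QC differed by 0.36 ± 0.15 and 0.45 ± 0.24. All 18 leukocyte markers had positive differences (median 0.27, camera adjusted p = 1.55e-06; adjusted p = 0.723 with an estimated correlation; score exact permutation p = 0.115). Of 37 oxidative phosphorylation genes, 36 had negative differences (median -0.12, camera adjusted p = 6.61e-06; adjusted p = 0.929 with an estimated correlation; score exact permutation p = 0.229, adjusted p = 0.943). Medians of the other called lists were 0.30 for immediate early genes, 0.24 for adipocyte markers, 0.12 for endothelial markers, 0.12 for matrix genes and -0.08 for the tricarboxylic acid cycle, and the 7 lists had adjusted p from 0.723 to 0.929 with an estimated correlation. Without pig 12, 3 lists passed, since the oxidative phosphorylation, adipocyte, matrix and tricarboxylic acid cycle lists ended; the adipocyte list also ended without pig 2 or 16. The matrix and tricarboxylic acid cycle lists each ended in 10 of 24 such runs. SNRPF, RTN3, MEA1, SPATS2L, ADRB3, RPL17, RSF1 and TMBIM6 had the smallest p, with differences from -0.65 (ADRB3, a receptor for catecholamines) to 0.43 (RTN3) and an adjusted p of 0.987. The limma fit passed 0 probe sets and 561 had an unadjusted p under 0.05; 1 passed without pig 14. The 13 genes named in every comparison ranged from -0.14 (MYH7) to 0.57 (ADIPOQ).

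Over the 6 pairs of fats, camera with the preset correlation called 36 of 132 list tests, and 0 with an estimated correlation. Of the list scores, 13 had an exact permutation p under 0.05 and 0 an adjusted one. With a smallest p of 0.005 over 132 tests, a score could pass only if many others also reached that p. Scores at that p had an adjusted p of 0.165. The lack of adjusted calls is thus no evidence against a difference between fats. Random regroupings of the pigs gave a median of 36 called lists, and a median of 6 where the contrast of unsaturated and saturated fats gave 7. Adipocyte markers and PPAR targets shared 1 tested gene (LPL), fatty acid oxidation and PPAR targets 4 (ACADVL, CPT1A, CPT1B, SLC25A20), and oxidative phosphorylation and the tricarboxylic acid cycle 2 (SDHA, SDHB).

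Whether the fats acted differently in gilts and barrows was tested by the interaction. LOC100621559, RNF13, HARBI1, SLC38A10, FOLH1B, VSTM4, MAP4 and PIK3IP1 had the smallest p, each with an adjusted p of 0.778, and did not pass. The 13 genes named in every comparison had adjusted p from 0.778 to 0.989. No probe set passed in limma and 895 had an unadjusted p under 0.05; 1 passed without pig 12, 14 or 18 and 2 without pig 24.

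Lists of fatty acid oxidation, PPAR targets, glycolysis and the interferon response differed between barrows and gilts, as did single genes of fat synthesis. The lipogenesis list as a whole did not pass (median 0.10; score difference 0.34, permutation p = 0.081, adjusted p = 0.198). EIF1AY, a Y-linked translation factor, was at 10.9 ± 0.11 on the log2 scale in barrows (SD, n = 12). All 12 gilts lay below the signal filter for it (mean 3.66 ± 1.10), so its difference has only a lower bound, at least 4.44 or 21.7-fold with each gilt set to the filter level (adjusted p = 1.8e-12). SCD and FASN rose by 2.11 ± 0.56 and 1.61 ± 0.41 (SE; adjusted p = 0.0369 and 0.0284) in barrows, where 9 of 12 pigs lay above the gilt mean; the spread of SCD was 2.11 in barrows and 0.90 in gilts (SD). ME1, which supplies reducing power for fat synthesis, rose by 0.96 ± 0.17, EGF, the epidermal growth factor, by 1.86 ± 0.22, and ARG2, the mitochondrial arginase, by at least 0.73 with 10 of 12 gilts below the signal filter and set to its level (1.59 ± 0.25 as measured). SLC37A4, a glucose 6-phosphate transporter, BPGM, which makes bisphosphoglycerate from a glycolytic intermediate, and MYF6, a myogenic transcription factor, rose by 1.36, 1.21 and 1.02. ZC3H11A and PAPOLA, which serve RNA export and polyadenylation, rose by 1.25 and 0.84. The probe set of ZFX, the X-linked partner of a Y-linked gene, was higher by 1.59. For these 9 genes, from ME1 to ZFX, 12 of 12 barrows lay above the gilt mean. They were chosen on this difference, and the sexes overlapped for ME1, ARG2, BPGM, MYF6 and PAPOLA. Whether the ZFX probe set also measures the Y-linked gene was not tested. The score of X-linked genes with a Y partner differed by -0.07 (permutation p = 0.182).

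Genes of the interferon response, which cells induce against viruses, were lower in barrows. RSAD2, an antiviral enzyme, fell by 1.77 ± 0.35 on the log2 scale (3.41-fold; lower than the gilt mean in 11 of 12 barrows), ISG15, a ubiquitin-like protein, fell by 1.20 ± 0.27, MX1, an antiviral GTPase, by a difference of -1.20 ± 0.24 and IFI44L by -0.88 ± 0.16. Of 15 members, 8 fell and 7 did not pass; 10 fell when adjusted over the list alone. The list median was -0.69 (camera adjusted p = 6e-07; adjusted p = 0.338 with an estimated correlation), and the score was 0.34 ± 0.45 in gilts and -0.34 ± 0.29 in barrows (SD, n = 12; permutation p = 0.000125, adjusted p = 0.00138). ISG12(A), a further interferon-induced gene outside the list, fell by 1.28 ± 0.24. The leukocyte score differed by -0.02 (permutation p = 0.907) and the endothelial score by -0.16 (permutation p = 0.0285, adjusted p = 0.104).

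Genes of fatty acid use were lower in barrows. HADHA and HADHB, the subunits of the mitochondrial trifunctional protein, differed by -0.80 ± 0.15 and -0.55 ± 0.14, ACADL, a long-chain acyl-CoA dehydrogenase, by -0.53 ± 0.11 and ACAA2, a thiolase, by -0.65 ± 0.15, all past the threshold. Of 25 fatty acid oxidation genes, 5 fell and 20 did not pass; 12 fell when adjusted over the list alone (median -0.28, camera adjusted p = 6e-07; adjusted p = 0.338 with an estimated correlation; score -0.33, permutation p = 0.000138, adjusted p = 0.00138). Of 11 PPAR targets, 4 fell. FABP3, the fatty acid carrier of muscle, ANGPTL4, an inhibitor of lipoprotein lipase, LPL, that lipase itself, and ACADVL, an acyl-CoA dehydrogenase, differed by -0.96, -1.09, -0.59 and -0.70. Adjusted over the PPAR list alone, 10 fell and 1 rose (median -0.56, camera adjusted p = 2.48e-05; adjusted p = 0.338 with an estimated correlation; score -0.47, permutation p = 0.000188, adjusted p = 0.00138). LIPE, the hormone-sensitive lipase, fell by 1.26 ± 0.35 and RBP7, a retinol carrier, fell by at least 0.94 with 6 of 12 barrows set to the signal filter (-1.56 ± 0.38 as measured). In the slow fibre list, CASQ2, the calcium store of slow and heart muscle, fell by at least 1.08 with 6 of 12 barrows set to the signal filter (-1.31 ± 0.28 as measured), while MYH7, the slow myosin, differed by -0.15 and did not pass. That list had a median of -0.15 (camera adjusted p = 0.0466; adjusted p = 0.804 with an estimated correlation; score -0.28, permutation p = 0.014, adjusted p = 0.0618; -0.15, permutation p = 0.116 without CASQ2), and no longer passed in 12 of 24 runs that left out a pig (1, 3, 4, 6, 7, 8, 11, 14, 20, 21, 22 or 23; median -0.10 without pig 11).

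Glycolytic genes were higher in barrows. TPI1 and GPI, isomerases of glycolysis, PGK1, a kinase of its energy-yielding part, and PHKB, a subunit of the kinase that starts glycogen breakdown, rose by 0.58 ± 0.10, 0.45 ± 0.11, 0.53 ± 0.11 and 0.69 ± 0.17. Of 19 members, 4 rose and 15 did not pass; 9 rose when adjusted over the list alone (median 0.27, camera adjusted p = 7.36e-06; adjusted p = 0.352 with an estimated correlation). The score was -0.12 ± 0.18 in gilts and 0.12 ± 0.12 in barrows (SD, n = 12; permutation p = 0.00025, adjusted p = 0.00138).

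**Figure D3:**
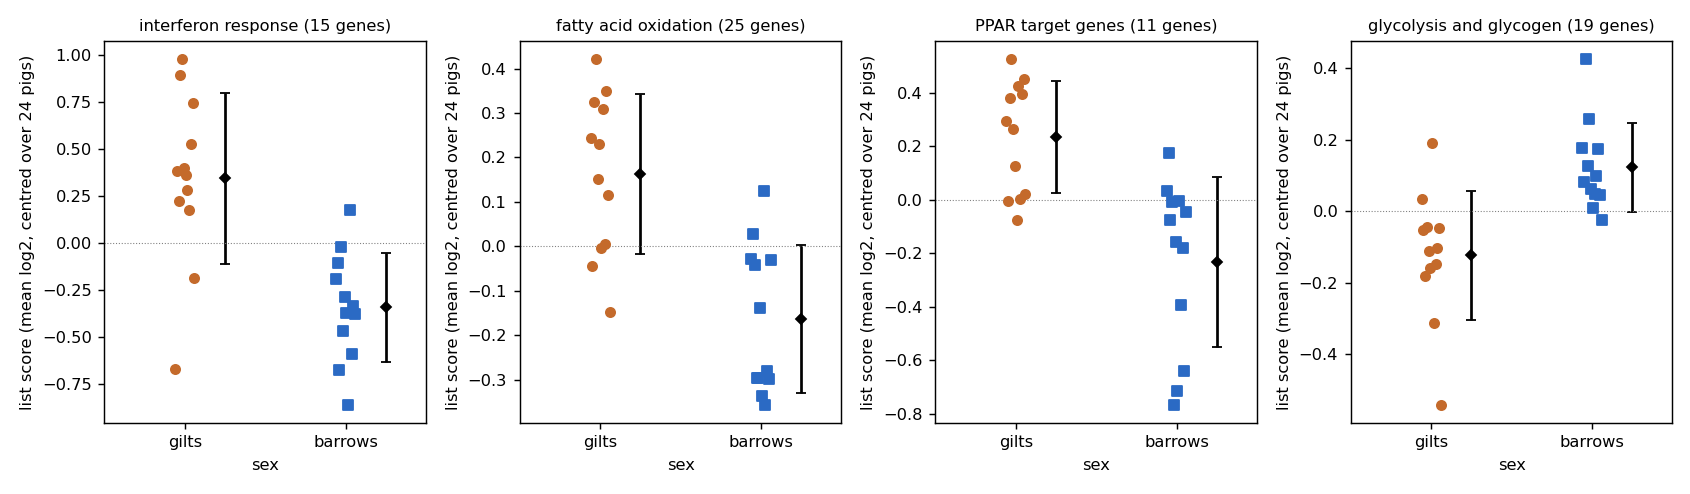
List scores per pig (mean log2 value of the list's genes, centred over the 24 pigs) for interferon response, fatty acid oxidation, PPAR target and glycolysis genes in 12 gilts (circles) and 12 barrows (squares); diamonds with bars are the mean ± SD of 12 pigs. Mean scores of the interferon list were 0.34 in gilts and -0.34 in barrows.

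Other genes that fell in barrows were MYO5B, a motor of vesicle transport, TMEM120A, SLC22A3, a transporter of organic cations, RHBDD2, S100A1, a calcium sensor of muscle, PLAC8 and FCN2, a lectin of innate immunity, with differences of -1.62, -1.44, -1.39, -1.33, -1.26, -1.25 and -1.21. For MYO5B and RHBDD2, 11 and 8 of the 12 barrows lay below the signal filter, and with these set to its level the falls were at least 1.02 and 0.52. Of the 13 genes named in every comparison, SCD, FASN and LPL passed; PPARG, CPT1B, PDK4, FABP4, ADIPOQ, MYH7 and IGF1 had differences of -0.47, -0.57, -0.33, -0.51, -0.80, -0.15 and -0.20, and UCP3, LEP and PPARGC1A of 0.62, 0.22 and 0.11. Besides EIF1AY, 6 probe sets with no gene symbol had all pigs of 1 sex below the signal filter and all of the other above it. They were singled out after their values were seen. Of these 6, 2 were higher in barrows (means 12.2 and 11.4, at least 55.5-fold and 30.4-fold) and 4 in gilts (means from 10.1 to 11.2, from at least 12.5-fold to at least 27.7-fold). SRY, the Y-linked sex-determining gene, lay below the signal filter in both sexes (4.83 in gilts and 4.99 in barrows).

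Medians of the lists that did not pass between the sexes were -0.54 for adipocyte markers, -0.23 for X-linked genes with a Y partner, -0.21 for matrix genes, -0.24 for immediate early genes, -0.10 for endothelial markers, -0.07 for the growth axis, 0.11 for fast fibre genes, 0.10 for lipogenesis, 0.10 for atrophy and FOXO targets, 0.06 for cholesterol synthesis, 0.03 for the circadian clock, 0.02 for the tricarboxylic acid cycle, 0.01 for ribosomal proteins, 0.01 for satellite cells and regeneration and 0.00 for oxidative phosphorylation. Leukocyte markers had a median of 0.00 and a mean of -0.02, and heat shock genes a median of -0.01 with camera on the positive side (adjusted p = 0.626). In the adipocyte list 2 genes fell and 1 rose; in the lipogenesis list 3 rose and 1 fell.

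With limma, 687 probe sets passed between the sexes, 326 higher and 361 lower in barrows, which stand for 314 named genes. In all, 3044 had an unadjusted p under 0.05. The share that was lower was 52.5% as deposited, 45.4% after quantile normalization and 37.9% (261 of 688) when each array was centred on its median. The count was 386 without pig 14, 393 without pig 8, 432 without pig 6, 434 without pig 17, 440 without pig 3, 448 without pig 23, 449 without pig 10, 452 without pig 4 and 1057 without pig 7, and 416 without the 3 least correlated arrays. SCD no longer passed without pig 1, 2, 3, 5, 6, 10, 11, 14, 17, 19, 21, 22, 23 or 24, FASN without pig 3, 14, 17 or 21, GPI without pig 8, 14 or 17, PHKB without pig 8 or 14 and MYF6 without pig 14. LIPE, FCN2, ACADVL, PLAC8 and HADHB were lost in 20, 17, 13, 11 and 10 of the 24 runs. The camera calls for 5 of 22 lists with the preset correlation were 0 with an estimated correlation, and random regroupings gave a median of 6; the list scores of interferon response, fatty acid oxidation, PPAR targets and glycolysis passed after adjustment over the 22 lists. All gilts have lower running numbers than all barrows, so any effect of the order of handling cannot be separated from sex.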

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

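The tests of array scaling were set before their results were seen; the tests by leaving out single pigs, those against the leukocyte, endothelial, adipocyte and slow fibre scores (the last also without each of its genes) and that of the order of handling were chosen after the results were seen, as were the searches for single pigs that stand apart.

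The extracellular matrix score was lower with coconut oil than with beef tallow by a difference of -0.73, with 7 of 22 genes past the threshold, while the medians of the arrays differed between these fats as well (-0.13). Array scaling as the whole cause is argued against, since the score difference was -0.60 after median centring and -0.73 after quantile normalization, each with the smallest exact permutation p of 0.005. A single pig as the cause is argued against, since the list median closest to 0 over the 24 runs without 1 pig was -0.63. Only runs without a pig fed coconut oil or beef tallow could move that median. A lower share of non-fibre tissue in the samples cannot be told apart from a change within fibroblasts. The matrix score fell beyond the endothelial score with an exact permutation p of 0.05 and beyond the leukocyte score with 0.135. Neither comparison separates these explanations. The adipocyte score differed by -0.90 between these fats (exact permutation p = 0.02, adjusted p = 0.264). It was not compared with the matrix score, so a lower share of fat tissue was not tested. The fat itself, the assigned factor, stays open: the exact permutation of the fats within each sex gave p = 0.005, the smallest possible (adjusted p = 0.165), and pens could not be allowed for.

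Interferon response genes were lower in barrows than in gilts (score difference -0.69). Scaling is argued against, since the difference was -0.64 after median centring (permutation p = 0.000488) and -0.65 after quantile normalization. Fewer leukocytes in the samples of barrows are argued against as well: the leukocyte score differed by -0.02, and the interferon score fell by more than it (permutation p = 0.00271), as it did beyond the endothelial score (-0.16; permutation p = 0.00804 for the gap). The order of handling cannot be told apart from sex, because 0 barrows had a running number below that of any gilt. Sex itself, including castration, stays open as an untested explanation.

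SCD and FASN were higher in barrows while fatty acid oxidation genes were lower. More fat cells in the samples of barrows are argued against, since the adipocyte score differed by -0.43 while the mean of SCD and FASN differed by 1.86 (permutation p = 7.5e-05 for the gap). A lower share of slow fibres in barrows cannot be told apart from a change within fibres: the slow fibre score differed by -0.28 and the oxidation score by -0.33 (permutation p = 0.602 for the gap), but this rests on CASQ2. Without that gene the slow fibre score differed by -0.15 (permutation p = 0.116), and the gap was -0.18 (permutation p = 0.0513). Sex itself stays open as an untested explanation, and the order of handling is confounded with it.

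Among 192 groups of 6 pigs (48 measures in 4 fats), 15 had a pig whose gap to its nearest neighbour was a larger share of the whole range than Dixon's test allows. Chance picks out about 1 in 20 groups, here 9.6. In the coconut oil group, pig 23 stood high in SCD (0.911 of the range; 12.5 against 8.33 for the next), in FASN (0.753) and in the lipogenesis score (0.772). Pig 15 of that group stood high in the glycolysis score (0.647) and pig 20 stood low in ADIPOQ (0.628). In the olive oil group, pig 12 stood low in its mean correlation with the other arrays (0.759), in the satellite cell score (0.727) and in CUL4A (0.672) and high in the leukocyte score (0.83). Pig 7 of that group stood low in FASN (0.681) and pig 4 stood low in the GAPDH ratio (0.696). In the soybean oil group, pig 11 stood low in its mean correlation (0.77) and in GLUL (0.735). In the beef tallow group, pig 16 stood high in the GAPDH ratio (0.658) and low in CUL4A (0.687).

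Differences between fats that were called by camera were compared between the sexes for 43 list scores, and 3 had an exact permutation p under 0.05, none after adjustment. The sexes were relabelled within each fat. These p therefore test for any sex difference in the fats compared and not for an interaction alone. The matrix score difference of olive oil minus beef tallow was lower in barrows than in gilts by a difference of -0.97 (exact permutation p = 0.04). The heat shock score difference of the same fats was higher in barrows by 0.37 (exact permutation p = 0.04), and the atrophy score difference of soybean minus olive oil was lower by a difference of -0.72 (exact permutation p = 0.035).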

How the results depend on the processing

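The alternative without the 3 least correlated arrays was chosen after the data were seen, as were median centring and the pseudocount for the gene lists; the other settings given here were planned. No called list and no named gene past the threshold reversed its direction; genes near 0 that had not passed changed sign in places, as UCP3 did for coconut oil minus beef tallow (-0.05, and 0.08 with median centring). Median centring turned the majority of the calls: 63 of 164 were lower for coconut oil minus beef tallow, against 124 of 161, and 261 of 688 for barrow minus gilt, against 361 of 687. For coconut oil minus beef tallow, 161 calls became 6 without the filter, 279 with the 60th percentile filter, 51 with quantile normalization, 0 with the additive model, 1264 with array weights, 65 with 1 probe set per gene (fewer probe sets tested), 313 with the arrays of both fats alone and 260 without the 3 arrays. For barrow minus gilt, 687 became 302, 1530, 291 and 416 with no filter, array weights, 1 probe set per gene and without the 3 arrays. Without the filter 2 passed for olive minus coconut oil, 3 for soybean minus coconut oil and 4 in the F test; with array weights 5 passed for soybean minus coconut oil and 68 in the F test. Soybean minus coconut oil gave 33 with both fats alone and 3 without the 3 arrays. The list calls were 0 for the fat pairs, 0 for unsaturated minus saturated and 0 for the sexes with an estimated correlation; without the 3 arrays unsaturated minus saturated gave 2. The causes of these changes were not tested. Leaving out each pig gave 0 to 664 calls for coconut oil minus beef tallow, 0 to 7 for olive oil minus beef tallow, 0 to 4 for soybean minus coconut oil, 0 to 1 for the other fat pairs and for unsaturated minus saturated, 386 to 1057 for the sexes, 0 to 25 in the F test, 0 to 2 for the interaction, and 3 to 10 lists for unsaturated minus saturated. For the named genes, 4006 values under the other alternatives kept their side of the threshold, 77 lost a call and 37 gained one. Leaving out pigs kept 9213, lost 275 and gained 40. Most of the 397 pairs of gene and test behind these values had not passed, and only those past the threshold can lose a call. These counts therefore do not show how firm the calls were, and those of coconut oil minus beef tallow were often lost, as given above. For the called lists, 262 values kept the call and 74 lost it, and leaving out pigs kept 1060 and lost 92. Dim genes such as SRY, PPARA and SREBF1 lay below the signal filter, so no difference is given for them.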

Other observations

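The regroupings of the pigs were set before their results were seen. They compare each count with those from 99 random regroupings within the other factor, the real grouping making 100.

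Chance is argued against for the size of the count of 161 in coconut oil minus beef tallow (1 of 100 groupings gave as many, highest other 1). The same holds for the count of 687 in barrow minus gilt (1 of 100, highest other 74). That share is the smallest possible with 100 groupings, and it speaks for the count and not for each probe set. The count of 161 also fell to 0 without some single pigs and with the additive model. Where no probe set passed, counts at an unadjusted p under 0.05 were compared. Taken 1 at a time, chance is argued against for the 1875 of soybean minus coconut oil (1 of 100, highest other 1689). Few groupings reached the 1275 of olive minus coconut oil (3 of 100, highest other 1692) or the 1676 of the F test (2 of 100, highest other 1975). Both of these shares lay under the bound of 0.05 that was set beforehand. Since other groupings gave more, chance is still left open here for the latter 2 counts. These shares are not adjusted for the number of counts tested, and these comparisons share the 6 pigs fed coconut oil. It cannot be excluded for the 928 of olive oil minus beef tallow (28 of 100; highest other 3289), the 498 of soybean oil minus beef tallow (83 of 100; highest other 1429), the 458 of soybean minus olive oil (90 of 100; highest other 1651), the 561 of unsaturated minus saturated fats (63 of 100; highest other 1946) and the 895 of the interaction (21 of 100; highest other 2234). A random regrouping for olive oil minus beef tallow called 708 probe sets with an adjusted p under 0.05 where the real one called 0, which points to a structure of the samples; what it is was not tested, and the median of these regroupings was 646 at an unadjusted p under 0.05.

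For the gene lists called with the preset correlation, chance cannot be excluded: the 36 of the fat pairs were reached by 51 of 100 groupings (highest other 53), the 7 of unsaturated minus saturated fats by 48 of 100 (highest other 12) and the 5 of the sexes by 72 of 100 (highest other 11). These counts carry no evidence of a difference, and the list scores per pig, tested by permutation, are the values to read. For the fat pairs, the smallest permutation p of 0.005 leaves an adjusted p little room to pass over 132 tests.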
